A study of Homo sapiens with 6 samples.

How the data were processed

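Gene expression was measured in DLD-1 cells, an established human colon cancer line, that had received by lentivirus either green fluorescent protein (GFP) or 5SA-Atoh1. 5SA-Atoh1 is a form of the transcription factor ATOH1 in which 5 serines were replaced by alanine to stabilise the protein, per the labels. Each group had 3 samples, named here by their group and replicate number. Total RNA was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols.

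The deposited files hold the fluorescence intensity of every spot on a linear scale, background-corrected by Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. Each array had 44495 spots, of which 43118 were not controls. No step after feature extraction had been applied to these intensities, and scaling between arrays was done here. The processed intensity was converted to log2, and the 75th percentile over the non-control spots of the same array was subtracted. Spots marked as outliers by the scanner software were left out (198 to 259 per array), and the spots of a probe were averaged. No spot was saturated. A probe was taken as well above background on an array when at least 0.5 of its spots were, and probes well above background on all 3 arrays of at least 1 group were kept.

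Probes were named through the accession that the files give. Symbols were taken from a RefSeq table of the GRCh38.p14 assembly, matched on the accession without its version. Of 34127 non-control probes, 25422 received a symbol and 8705 did not. The file headers name another assembly (hg19), so only names and the order of neighbouring genes were taken from the table and no coordinates are given. Of the 19483 genes with a probe, 14736 were tested, each through its probe with the highest mean signal over the 6 arrays.

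Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. A further count required a log2 fold change of at least 1. Gene lists were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 29 lists, and again with a correlation estimated from the data. Camera asks whether the genes of a list moved relative to all other genes tested. Limma's fry, planned beside it, tests a list without reference to the other genes, by direction and in any direction (mixed). Where every array of a group lacked a signal well above background, a fold is given as a lower bound ("at least N-fold"). The bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.

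The groups, the tests, the alternatives below, the 29 gene lists and the rule for naming genes were fixed before the data were examined. The rule named 12 genes whatever their values, then the 12 largest rises and the 12 largest falls among genes past the threshold that were well above background on all 6 arrays and whose groups did not overlap. It further named the 6 largest bounds in each direction, and up to 4 members of each list that was called or in which at least 25% of the measured genes passed, otherwise up to 2. A gene that the rule names is not reported here. Other list members named in the text were chosen after their values were seen. The lists covered secretory lineage transcription factors, goblet, Paneth, enteroendocrine, tuft, enterocyte and stem cell genes, mucins, O-glycosylation enzymes, protein folding in the endoplasmic reticulum and the integrated stress response. They also covered WNT targets, NOTCH ligands, NOTCH receptors and targets, sensory hair cell genes, early neuronal genes, bHLH partners and inhibitors, S phase genes, G2 and mitosis genes, CDK inhibitors and p53 targets. The remaining lists were drug transport, epithelial-mesenchymal transition, interferon-stimulated, inflammatory and immediate early genes, cholesterol synthesis, and markers of immune cells and of fibroblasts and endothelium.

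The alternatives fixed at the same time were normexp background correction with an offset of 50, quantile normalization, scaling by the median or by the 75th percentile of detected probes, and both looser and stricter filters on dim probes. Others kept the outlier spots, averaged the probes of a gene, fitted the variance with a trend and robustly, weighted arrays, added the replicate number or the slide as a block, and left out each replicate in turn. Normexp was run on the spot medians and background medians, since the files hold no column of spot means. The array weights stopped before full convergence. Chosen after the data had been seen were a comparison within slide 1, scaling to the spike-in control spots, tests of unnamed transcripts and of gene families, and a run without genes that lie in shifted runs of neighbours. The filter on dim probes was repeated on the 4 arrays of slide 1 for the counts of genes and for the alternatives, while the adjusted p of lists in the report within slide 1 kept the 14736 genes.

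The file headers place the 3 GFP arrays and 5SA-Atoh1 replicate 1 on 1 slide and the remaining 5SA-Atoh1 arrays on another, and each slide was scanned on its own. With the slide as a block, the difference between the groups comes from slide 1 alone, where the lone 5SA-Atoh1 sample is assumed to vary like the GFP samples. The 75th percentile signal ranged from 733.2 to 884.6 units, the median signal from 93.7 to 119.4, and 68.6 to 73.5% of spots were well above background. The number of arrays limits the precision. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

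The limma and camera steps were tested on simulated gene values for the comparison of 5SA-Atoh1 with GFP, with 200 of 14736 genes changed, 50 of them at each size. Scaling, averaging of spots and filtering were not part of this test. Limma recovered 28% of the genes changed by 0.25 on the log2 scale, 66% at 0.5, 82% at 1 and 96% at 2, with 5 false calls. These rates hold where few genes change. In the real data 64% of the genes passed, so the rates do not carry over to it. In simulated data without any shifted list 0 lists were called, and 1 was called when the goblet list was shifted by 0.5. The simulated genes varied independently of each other. The list result therefore does not show how camera behaves where genes of a list vary together.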

Results

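The arrays compared DLD-1 colon cancer cells expressing 5SA-Atoh1 with DLD-1 cells expressing GFP, 3 samples in each group, to find the genes whose transcripts differed when stabilised ATOH1 was present. ATOH1 is the bHLH transcription factor that directs intestinal progenitors to the secretory lineage. Values below are log2 fold changes (5SA-Atoh1 minus GFP) ± SE from limma with n = 3 arrays per group, with adjusted p-values over all genes tested, unless stated otherwise. Arrays of the same group correlated at 0.994 to 0.997 across genes and arrays of different groups at 0.962 to 0.967, and the first principal component held 86.9% of the variance. The median SD between arrays of a group was 0.073 on the log2 scale over all genes tested, dim ones included. Between the 10 spots of a probe printed repeatedly on an array it was 0.081. The latter was taken only over such probes well above background on every array, so these values do not cover like probes.

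The transcript of ATOH1 itself, measured by a single probe, was 6.60 ± 0.49 higher in the 5SA-Atoh1 samples (adjusted p = 0.000124). It was well above background on all 3 5SA-Atoh1 arrays and on 1 of 3 GFP arrays. With the slide as a block the difference was 6.50. The labels do not give the species or the transcript ends of the construct, so the probe may measure the introduced transcript, the cell's own, or both.

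Of 14736 genes tested, 4345 were higher and 5084 lower in 5SA-Atoh1 cells. At least 2-fold changes were seen for 515 genes that were higher and 793 that were lower, while 6186 of the 9429 genes past the threshold changed by less than 1.5-fold. With the slide as a block, 3447 genes were higher and 3779 lower, and 539 and 749 at least 2-fold. Within slide 1 the counts were 2947 higher and 3318 lower, with 579 and 745 at least 2-fold. The balance of 2-fold rises and falls did not hold across the processing: it was 317 and 283 with normexp, 428 and 484 with the stricter filter, 670 and 631 under median scaling, and 1189 and 441 under spike-in scaling. The direction split followed the scaling. Of the genes called, 46.1% were higher under the main scaling, 61.3% (5562 higher, 3513 lower) after scaling to the median, and 83.3% (6427 higher, 1286 lower) after scaling to the spike-in RNA. Spike-in spots were 2.77 ± 0.17 above the 75th percentile on GFP arrays and 2.41 ± 0.14 on 5SA-Atoh1 arrays (SD, n = 3 each), and scaling to them moved the median change of all genes from −0.05 to 0.31. Changes are therefore relative to the 75th percentile of each array. Under the spike-in scaling, which raises every gene alike, of the list medians below 0 those of the inflammatory genes (−0.09) and tuft cell genes (0.00) did not rise above it.

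**Figure D1:**
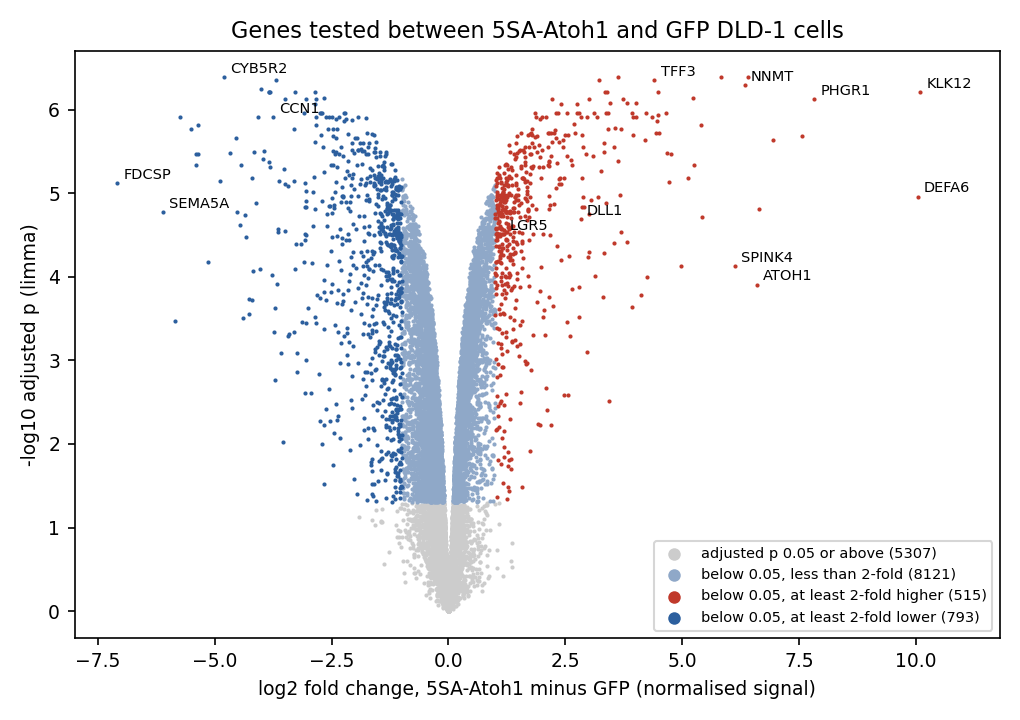
Each point is a tested gene, with the log2 fold change of 5SA-Atoh1 over GFP on the x axis and −log10 of the limma adjusted p on the y axis, 3 arrays per group; for genes not well above background in a group, such as KLK12, the x value is the fitted difference and not a measured fold. Red points are the 515 genes at least 2-fold higher and dark blue points the 793 at least 2-fold lower, light blue points changed less, and grey points did not pass.

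Genes of the goblet cell, the mucus-secreting cell of the intestine, were mostly higher in 5SA-Atoh1 cells. Of 31 measured, 17 rose, 8 fell and the others did not pass, with a median of 0.39. TFF3, a trefoil peptide secreted with mucus, rose by 4.41 ± 0.05 (adjusted p = 4.41e-07) and went from 2.03 ± 0.05 above the 75th percentile in GFP cells to 6.44 ± 0.05 (SD, n = 3); its 3 probes rose by 1.30 to 4.41. SPINK4, of the Kazal-type inhibitor family, rose by 6.13 ± 0.40 and its relative SPINK1 22.7-fold. SERPINA1 rose by 2.25 ± 0.05, and AGR2, a folding enzyme for mucins, rose by 1.52. MUC2, the main gel-forming mucin of the gut, did not rise: its brightest probe fell by 0.60 ± 0.16 (adjusted p = 0.0169) and its other 2 kept probes did not pass (−0.14 and −0.01). The MUC2 change did not pass with the slide as a block (−0.47, adjusted p = 0.139) nor when GFP replicate 2 or 5SA-Atoh1 replicate 3 was left out (adjusted p = 0.0565 and 0.0563), nor under spike-in scaling (adjusted p = 0.225). The goblet list was called by camera (p = 0.0032, adjusted p = 0.023), with adjusted p = 0.75 with an estimated correlation. Its median was 0.31 with the slide as a block and within slide 1 (adjusted p = 0.011 and 0.010), and without genes in shifted runs of neighbours (described further on) the call was lost (0.29, adjusted p = 0.099), as it was under median scaling (0.51, adjusted p = 0.0762) and with array weights (0.37, adjusted p = 0.0675).

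Transcription factors of the secretory lineage showed 10 members that rose and 4 that fell of 16 measured (median 0.44). SPDEF and GFI1, which act after ATOH1 in goblet and Paneth cell formation, rose by 1.31 ± 0.07 (adjusted p = 3.11e-05) and 1.14 ± 0.12 (adjusted p = 0.000469). FOXA2 rose by 1.66 ± 0.05, XBP1, a regulator of secretory capacity, by 1.08 and ELF3 by 0.96, whereas PAX6 fell by 0.70. Camera called the list (p = 0.0085, adjusted p = 0.049), with adjusted p = 0.75 with an estimated correlation; with the slide as a block and within slide 1 the median was 0.46 (adjusted p = 0.035 and 0.030). The call was lost with the stricter filter (0.22, adjusted p = 0.118), median scaling (adjusted p = 0.0729), array weights (adjusted p = 0.0675), the mean of probes (adjusted p = 0.0578) and the replicate block (adjusted p = 0.0503), and without GFP replicate 3 or 5SA-Atoh1 replicate 1. The list holds ATOH1, and without it the median was 0.22 and the list was not called (adjusted p = 0.088).

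**Figure D2:**
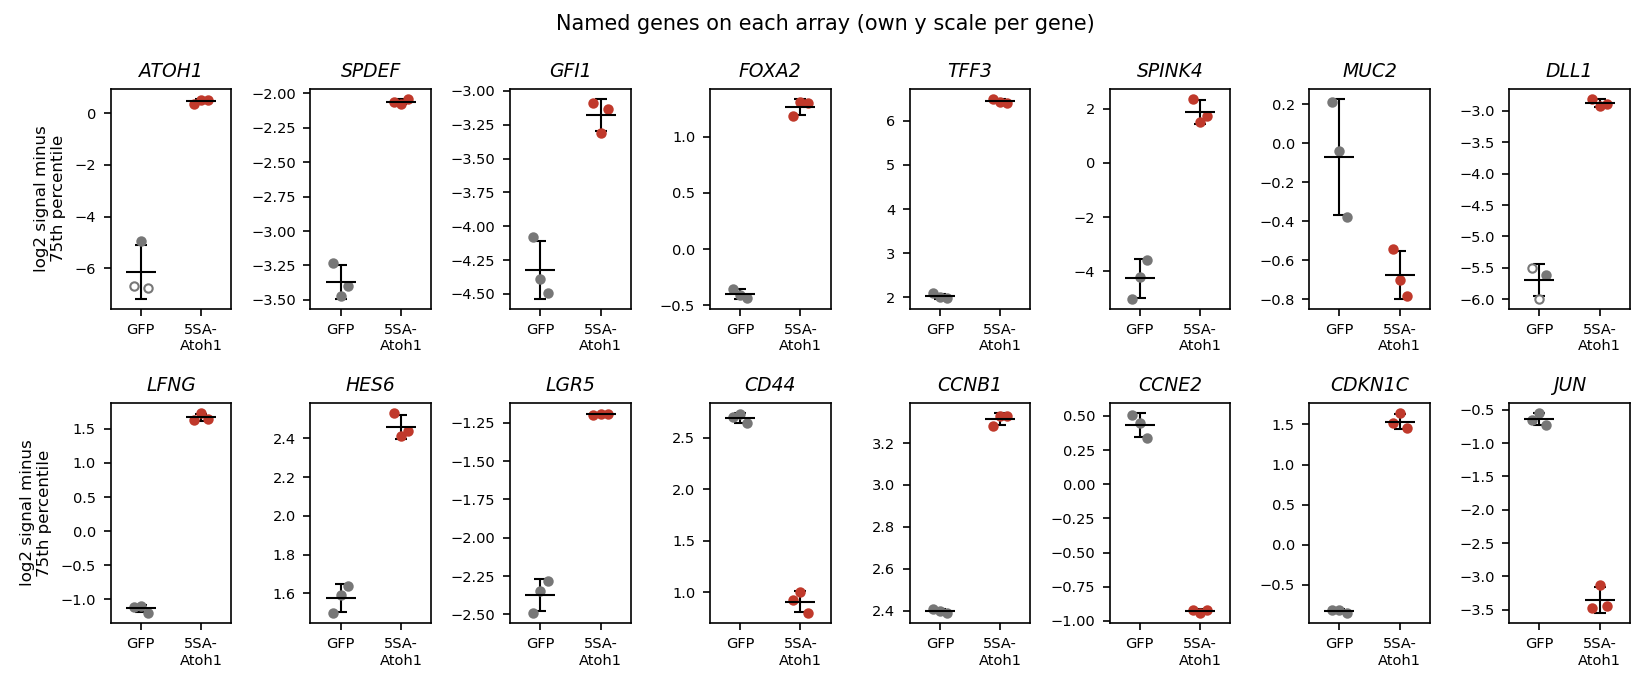
Each panel shows a gene on the 6 arrays, with the log2 signal minus the array's 75th percentile on the y axis (own scale per gene); points are arrays, open points were not well above background, and bars are the mean ± SD of 3 arrays. TFF3, SPDEF, GFI1, FOXA2, DLL1, LFNG, HES6, LGR5, CCNB1 and CDKN1C were higher in 5SA-Atoh1 cells (red), and MUC2, CD44, CCNE2 and JUN were lower.

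Among NOTCH ligands and their regulators 10 genes rose and 3 fell of 18 measured (median 0.25; adjusted over the list alone, 10 rose and 4 fell). The ligand DLL1 rose by 2.83 ± 0.13 (adjusted p = 2.06e-05) from a level that was well above background on 1 of 3 GFP arrays, JAG2 rose by 1.64 ± 0.06, and DLL4 was at least 2.37-fold higher. LFNG, a glycosyltransferase that modifies NOTCH, rose by 2.80 ± 0.05 through its brightest probe and by 0.67 through the other. DLL3, well above background on 1 of 3 GFP arrays, rose by 1.75 ± 0.42, a change that did not pass with the slide as a block (1.59, adjusted p = 0.0918). HES6, a bHLH gene activated by proneural factors, rose by 0.88 ± 0.06 (adjusted p = 6.22e-05). By camera the list as a whole was not called (adjusted p = 0.096), but was with the slide as a block (0.35, adjusted p = 0.043) and without genes in shifted runs (adjusted p = 0.039). With all genes and no block it had adjusted p = 0.75 with an estimated correlation. NOTCH receptors and targets moved in different directions, 5 rising and 6 falling of 20 (median −0.13, adjusted p = 0.78). HES1, a NOTCH target that represses ATOH1, rose by 0.79 ± 0.19 (adjusted p = 0.0135), and adjusted p was 0.0511 when GFP replicate 2 was left out. ID1 rose by 1.25 ± 0.05, while NRARP fell by 0.82 ± 0.06 and NOTCH4 by 1.23 ± 0.20. Of 13 bHLH partners and inhibitors 7 rose and 1 fell (median 0.50, adjusted p = 0.26): BHLHE40 rose by 1.56 and ID3 by 0.81, and TCF4 fell by 1.21.

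Marker genes of the other intestinal lineages did not move together relative to all other genes by camera. By fry, which has no such reference, the directional adjusted p was 0.00035 for Paneth, 0.11 for enteroendocrine, 0.0038 for tuft and 0.00081 for enterocyte genes. The direction that fry found was not recorded and need not be that of the medians below. Fry was run on the lists under the main scaling only. Adjusted p-values of lists below are again those of camera. Paneth cell genes had 5 risers and 4 fallers of 15 (median 0.20, adjusted p = 0.63). The median was 0.04 with the slide as a block and −0.02 to 0.38 over left-out replicates. Among the risers was DEFA6, an antimicrobial defensin, at least 348-fold higher and not well above background in any GFP sample. REG4 rose by 2.65 ± 0.08 and PRSS2 by 3.45 ± 0.05, whose probe may also bind transcripts of near-identical trypsinogen genes; SOX9 fell by 0.73. Enteroendocrine genes had 4 risers and 10 fallers of 23 (median −0.23, mean 0.00, adjusted p = 0.55): VWA5B2 rose by 5.14 ± 0.17 and SYT7 by 1.03, and CPE, a prohormone-processing enzyme whose chromosomal neighbours were also lower, fell by 1.84. Of 11 tuft cell genes 2 rose and 5 fell (median −0.37, adjusted p = 0.57), with KIT, also within a run of lower neighbours, 3.19-fold lower. Enterocyte and colonocyte genes had 6 risers and 9 fallers of 26 (median −0.24, mean 0.10, adjusted p = 0.80). The brush border genes DPP4 and VIL1 rose by 3.23 ± 0.03 and 3.01 ± 0.04.

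Intestinal stem cell genes were split evenly, 9 rising and 9 falling of 22 (median −0.08, mean 0.11, adjusted p = 0.78). LGR5, the receptor that marks crypt base stem cells, rose by 1.18 ± 0.06 (adjusted p = 3.11e-05), ZNRF3 rose by 1.22 ± 0.05 and ALCAM was 2.74-fold higher, while CD44 fell by 1.78 ± 0.06. WNT/beta-catenin targets, which share some of these genes, had 6 risers and 11 fallers of 28 (median −0.04, adjusted p = 0.62), with AXIN2 falling by 0.35 and MYC at 0.00 ± 0.04 (adjusted p = 0.928; −0.22 and adjusted p = 0.00681 under quantile normalization, 0.36 and adjusted p = 0.0441 under spike-in scaling). In other tissues ATOH1 acts in sensory hair cells and neuronal precursors. Of 26 hair cell genes 9 rose and 10 fell (median −0.15, mean 0.11, adjusted p = 0.80), with XIRP2 at least 3.82-fold higher and ANXA4 1.29 ± 0.03 higher. Of 20 early neuronal genes 4 rose and 5 fell (median −0.25, adjusted p = 0.78; adjusted over the list alone, 3 rose and 4 fell), with MYT1, whose neighbours were also higher, at least 6.23-fold higher and BARHL1 falling by 1.07 ± 0.13.

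Cell cycle genes moved in opposite directions by phase. Of 35 S phase genes 24 fell and 3 rose (median −0.19): CCNE2, the cyclin that drives entry into S phase, fell by 1.36 ± 0.05 (adjusted p = 1.13e-05), BRIP1 by 0.75 ± 0.12 (not past the threshold under spike-in scaling, adjusted p = 0.0922), UNG by 0.74 and DTL by 0.74, while POLA1 rose by 0.66. Of 34 G2 and mitosis genes 19 rose and 3 fell (median 0.16): the mitotic kinases PLK1 and AURKA rose by 1.11 ± 0.07 and 0.75 ± 0.05, CENPF rose by 0.61 and CCNB1 by 0.91 ± 0.03 (0.18 through its other probe). The proliferation marker MKI67 stood at 0.07 ± 0.05 (adjusted p = 0.27), and passed under median scaling (0.19, adjusted p = 0.0402) and spike-in scaling (0.44, adjusted p = 0.0174). Both lists were called, S phase with p = 0.0014 and adjusted p = 0.013 (adjusted p = 0.75 with an estimated correlation) and G2 and mitosis with p = 0.00062 and adjusted p = 0.009 (adjusted p = 0.49 with an estimated correlation). With the slide as a block and within slide 1 the medians were −0.21 and 0.14, with adjusted p = 0.011 and 0.010 for either list. The S phase call was lost under median scaling (−0.06, adjusted p = 0.0729), and its median turned to 0.18 under spike-in scaling (adjusted p = 0.24), and the G2 and mitosis call was lost under quantile normalization (0.02, adjusted p = 0.185). The difference between the 2 medians, which no scaling factor moves, was 0.35. CDK inhibitors and other genes of cell cycle exit had 7 risers and 7 fallers of 19 (median 0.10, adjusted p = 0.78). CDKN1C rose by 2.36 ± 0.06, GADD45G by 1.76 ± 0.06 and BTG2 by 1.28, CDKN2C fell by 1.63 ± 0.05 and BTG1 by 1.38, and CDKN1A was −0.13 ± 0.10 (adjusted p = 0.264) among neighbours that were lower. Of 21 p53 targets 5 rose and 6 fell (median −0.05, adjusted p = 0.96), with GDF15 2.34-fold higher and TIGAR falling by 0.73.

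Cholesterol synthesis genes were higher as a group, 17 rising and 3 falling of 22 (median 0.25). LSS rose by 1.19 ± 0.04 (adjusted p = 8.82e-06), FDFT1 by 0.67 ± 0.04 and DHCR7, within a run of higher neighbours, 1.76-fold. The list was called (p = 0.00045, adjusted p = 0.009), with adjusted p = 0.75 with an estimated correlation, and its median was 0.28 with the slide as a block and within slide 1 (adjusted p = 0.011 and 0.010). It was not called under spike-in scaling (0.62, adjusted p = 0.0548). Genes of translocation and protein folding in the endoplasmic reticulum had 19 risers and 8 fallers of 39 (median 0.15, adjusted p = 0.14). The risers were small, such as SSR4 by 0.40 and HYOU1, in a run of higher neighbours, by 0.53, and the main chaperone HSPA5 was 2.08-fold lower. Of 19 integrated stress response genes 3 rose and 12 fell (median −0.26, adjusted p = 0.25), with NUPR1 falling by 1.65 ± 0.10 and DDIT3 by 0.70 ± 0.09.

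Mucins were measured for 7 genes, of which 1 rose and 3 fell (median −0.35, adjusted p = 0.57). MUC13, a membrane mucin, was at least 4.93-fold lower, OVGP1 was 1.54-fold higher, and MUC6 fell by 0.35 ± 0.08. The MUC6 change did not pass with the slide as a block (−0.38, adjusted p = 0.0582), within slide 1 or with the mean of its probes (adjusted p = 0.0843), and stood at 0.01 under spike-in scaling. Enzymes of mucin-type O-glycosylation had 7 risers and 12 fallers of 30 (median −0.14, adjusted p = 0.74). The sialyltransferases ST6GALNAC2 and ST3GAL1 fell by 3.83 ± 0.05 and 2.41 ± 0.08, and the fucosyltransferase FUT3 rose by 2.41 ± 0.15.

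**Figure D3:**
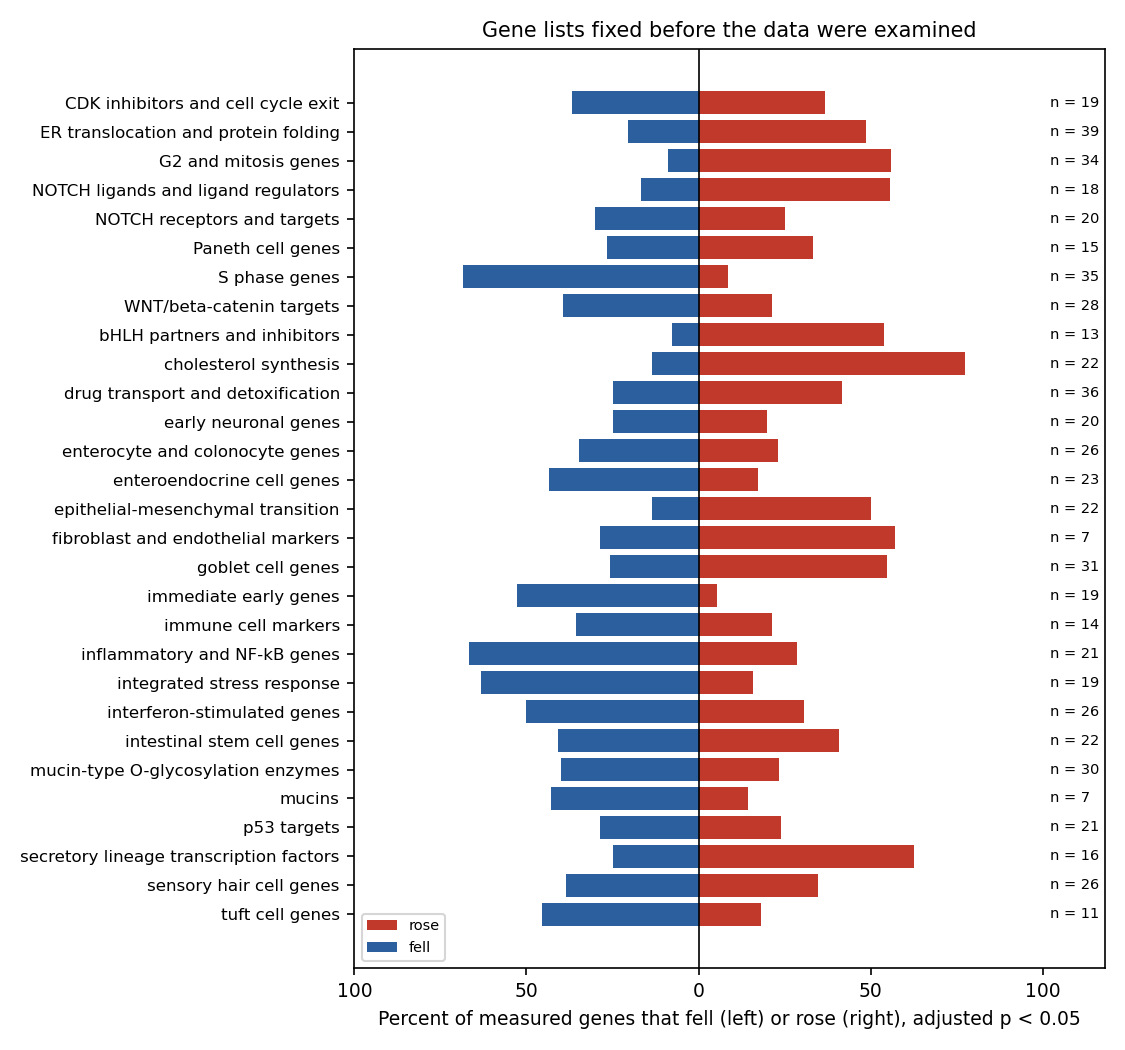
Bars give, for each of the 29 gene lists, the percent of measured genes that rose (red, right) or fell (blue, left) in 5SA-Atoh1 cells at a limma adjusted p below 0.05, with the number of measured genes (n) at the right. Risers outnumbered fallers by 17 to 3 among cholesterol synthesis genes and by 19 to 3 among G2 and mitosis genes, and fallers outnumbered risers by 24 to 3 among S phase genes, a split that depends on the scaling.

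Immediate early genes had 1 riser and 10 fallers of 19 (median −0.16, adjusted p = 0.051), and the list was called with the slide as a block (−0.26, adjusted p = 0.015) and, with its median at 0.21, under spike-in scaling (adjusted p = 0.022). Under spike-in scaling the median of all genes was 0.31, so the list was again called as lower than the other genes. In the main setting the list had adjusted p = 0.82 with an estimated correlation. CCN1 and CCN2, targets of the coactivator YAP, fell by 3.76 ± 0.07 and 3.53 ± 0.11, JUN by 2.71 ± 0.11 and FOS by 0.92 ± 0.06. Inflammatory and NF-kB genes had 6 risers and 14 fallers of 21 (median −0.46, adjusted p = 0.24; adjusted over the list alone, 6 rose and 15 fell). The inflammatory list was called under spike-in scaling (−0.09, adjusted p = 0.022), and in the main setting had adjusted p = 0.82 with an estimated correlation. PTGS2, which makes prostaglandins, was at least 4.46-fold lower and NOS2, well above background on 2 of 3 5SA-Atoh1 arrays, fell by 2.61 ± 0.13, whereas LCN2 rose by 0.92. Of 26 interferon-stimulated genes 8 rose and 13 fell (median −0.24, adjusted p = 0.55; adjusted over the list alone, 8 rose and 15 fell), with IFIT1 rising by 1.35 ± 0.07 and IFIT2 falling by 1.13 ± 0.11. Of 36 genes of drug transport and detoxification 15 rose and 9 fell (median 0.04, mean −0.01, adjusted p = 0.46): the efflux pump ABCB1 rose by 1.45 ± 0.08 and ALDH3A1 2.83-fold, while UGT1A6, whose probe may bind other UGT1A transcripts, fell by 2.51 ± 0.07 and SLC47A1, well above background on 1 of 3 5SA-Atoh1 arrays, fell by 3.31. Of 22 genes linked to epithelial-mesenchymal transition 11 rose and 3 fell (median 0.10, adjusted p = 0.25). The list was drawn up from both epithelial and mesenchymal genes, so its counts and median cannot show a transition or its absence. TGFBI rose by 1.07 ± 0.05, and the tight junction genes CLDN7 and CLDN4 by 0.94 ± 0.04 and 0.88 ± 0.06, while OCLN, also of tight junctions, fell by 1.69 ± 0.06.

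Markers of cell types that the cultures should not hold showed single large changes and no common shift relative to all other genes by camera. Of 14 immune cell markers 3 rose and 5 fell (median −0.22, mean 0.26, adjusted p = 0.96): CSF1R, a receptor of macrophages, rose by 5.24 ± 0.07 and CD14 by 1.10 ± 0.06, and CD68 fell by 0.61 ± 0.07, which did not pass under spike-in scaling (adjusted p = 0.144). Of 7 fibroblast and endothelial markers 4 rose and 2 fell (median 0.29, adjusted p = 0.35), with VWF 1.59 ± 0.05 higher and PECAM1 at least 2.03-fold higher. For every list not mentioned with its own count, the counts of risers and fallers adjusted over the list alone equalled those over all genes, and camera called 0 of the 29 lists with an estimated correlation, of which 1 had an unadjusted p below 0.05. By fry, 24 of the 29 lists passed by direction and 29 in any direction (adjusted p below 0.05). With 64% of all genes tested past the threshold, a pass by fry does not set a list apart from the other genes.

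The largest rise among genes measured on all 6 arrays was that of PHGR1 (7.83 ± 0.11, adjusted p = 7.43e-07), followed by NNMT (6.34 ± 0.07), which lies in a run of higher neighbours, SPINK4 and ANGPT1 (5.83 ± 0.05). DEFB1, an epithelial defensin, rose by 4.67 ± 0.12 and CELA3A by 4.43 ± 0.10, the latter through a probe that may bind its near-identical relative. The other genes in this class were CSF1R, VWA5B2, SPINK1, LPXN, TFF3 and CHRNA1, the last also in a run of higher neighbours. The largest falls were those of CYB5R2 (−4.80 ± 0.04, adjusted p = 4.13e-07; −3.09 through its other probe), CRTAM (25.7-fold), SERPINE2, a protease inhibitor (−4.01 ± 0.05), and CAV1, the coat protein of caveolae (−3.85 ± 0.05). ST6GALNAC2, PCP4, ZNF605, CCN1, PPP1R14C, CCN2, SCD5 and PLCE1 followed, with changes between −3.83 and −3.49; SCD5 lies in a run of lower neighbours.

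Some genes were well above background in all samples of a group and in none of the other. In this way 68 genes were seen in 5SA-Atoh1 samples and 252 in GFP samples. These counts rest on the tested probe of each gene, and other probes may have been detected. Fewer spots were well above background on 5SA-Atoh1 arrays (68.6 to 72.3%) than on GFP arrays (72.2 to 73.5%), with a slight overlap, which may add to the larger count in GFP samples. The largest bounds among those seen with 5SA-Atoh1 were at least 732-fold for the kallikrein protease KLK12, 348-fold for DEFA6, 46.9-fold for TUSC3, 33.9-fold for LRRC74B and 26-fold for KLK11, followed by RNF186. In the other direction they were at least 61.9-fold for FDCSP, 35-fold for SEMA5A, 24.6-fold for DACT1, an inhibitor of WNT signalling, and 15.6-fold for ADGRF1 and CHRM3. FDCSP, DACT1 and ADGRF1 lie in runs of lower neighbours.

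Changes were also arranged along the chromosomes. On chromosome 4, 335 of 488 tested genes (68.6%) fell and 43 rose, with a median of −0.43, and their mean level per array went from −0.88 ± 0.01 to −1.40 ± 0.02 (SD, n = 3 each). On chromosome 14, 299 of 463 genes (64.6%) fell and 30 rose (median −0.34). For each of 14713 placed genes the median change of its 50 nearest tested neighbours was taken. It differed from the median of all genes by more than 0.3 for 1467 genes (9.97%), 612 with higher and 855 with lower neighbours, against at most 34 in 100 random orders of the genes. Of the 1308 genes changed at least 2-fold, 182 (13.9%) lay in a run of their own direction. The longest runs were lower from LIMCH1 to SLC39A8 (155 genes, median −0.51, 114 fell and 12 rose) and from ALPK1 to FRG2 (158 genes, −0.49) on chromosome 4, and from TRMT5 to TMED10 on chromosome 14 (92 genes, −0.47). They were higher on chromosome 11 from CTSF to FAM76B (187 genes, 0.44, 120 rose and 24 fell) and from C11orf65 to UBASH3B (101 genes, 0.47). Within slide 1 these medians were −0.47, −0.47, −0.41, 0.45 and 0.48 in the same order. Without the genes in such runs, 3885 genes were higher and 4429 lower of 13269 tested, and 440 and 658 at least 2-fold.

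**Figure D4:**
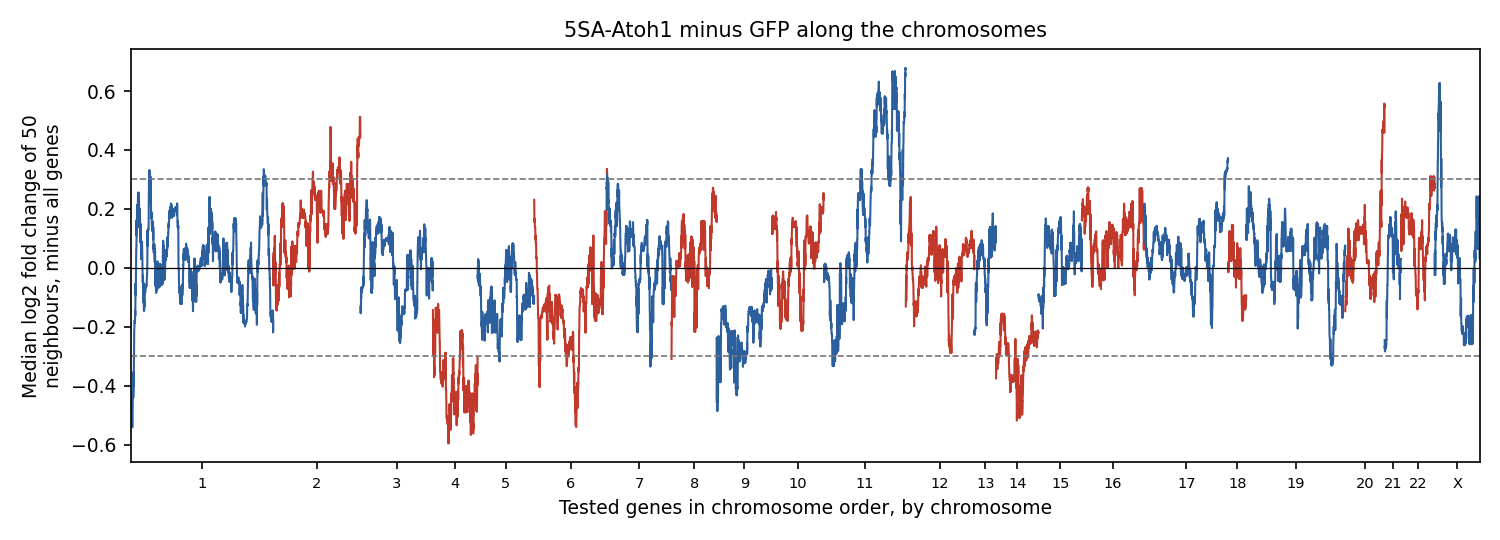
The line gives, for each tested gene in chromosome order (x axis, chromosomes in alternating colours), the median log2 fold change of its 50 nearest tested neighbours minus that of all genes (y axis, 3 arrays per group), with dashed lines at 0.3 and −0.3. Long stretches lie below the lower line on chromosomes 4 and 14 and above the upper line on chromosome 11, with the largest window 0.68 from all genes.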

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

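The comparisons with the slide and the scaling, and the within-group spread, were chosen as tests after the result was seen, and the count over other splits of the arrays before it.

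Probes whose accession has no symbol in the reference table stayed outside the comparisons of named genes, and they carried a difference between the groups. Of 4701 such transcripts tested with limma, 591 were higher and 1009 lower in 5SA-Atoh1 cells, and 104 were at least 2-fold higher and 138 at least 2-fold lower.

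The share of genes past the threshold was large, 9429 of 14736. A difference between the slides as the cause is argued against by the slide block, under which 73.7% of the genes called kept their call and direction. The split between higher and lower genes follows the scaling, since the percent of called genes that were higher ran from 38.9 to 83.3 over the scalings tried. The within-group SD of 0.073 gives no measure of the spread between separate cultures, so samples taken from a single culture per group may account for part of the count, and an effect of 5SA-Atoh1 stays open beside this. Only 1 of the 10 splits of the 6 arrays, the real one, gave as many higher, lower or 2-fold genes (highest other 0 for each, with at most 480 genes at an unadjusted limma p below 0.05), and 10 splits are too few for a share under 0.05. A regrouped split puts the difference between the groups into the spread within each side, so low counts there follow whatever caused that difference.

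Gene lists were called less selectively. For the count of lists, 2 of the 10 splits gave as many as the real one, with 5 lists in the real split and 5 in the split of GFP replicates 1 and 3 with 5SA-Atoh1 replicate 1 against the rest, and again the splits are too few for a share under 0.05. That split partly follows the slides, since its first side lies on slide 1 alone and its other side holds both arrays of slide 2. Splits with 1 array of slide 2 on each side still called 0 to 4 lists. The 4 were called for GFP replicates 1 and 3 with 5SA-Atoh1 replicate 3 against the rest. List calls at the preset correlation thus also arose in groupings that do not follow the slides. With the slide as a block, the 5 lists called kept their call.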

How the results depend on the processing

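The comparison within slide 1, the spike-in scaling and the test without genes in shifted runs were chosen after the data were seen. ATOH1 kept its direction and its call in every alternative that measured it; it was not tested among probes well above background on all 6 arrays nor outside shifted runs. The 4 counts of genes stayed within 1.5 times in all alternatives except these. Normexp gave 317 genes at least 2-fold higher and 283 lower, and the stricter filter, which tests fewer genes, gave 484 at least 2-fold lower. Within slide 1, with fewer samples, 3318 genes were lower. Spike-in scaling gave 1286 lower genes, with 1189 at least 2-fold higher and 441 at least 2-fold lower. Leaving out each replicate gave 3653 to 4202 higher genes, 4219 to 5074 lower, 506 to 555 at least 2-fold higher and 749 to 867 at least 2-fold lower.

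List calls were lost as follows, each with its median. With an estimated correlation none of the 5 called lists passed: secretory factors 0.437, goblet 0.387, S phase −0.187, G2 and mitosis 0.163, cholesterol synthesis 0.254, with adjusted p = 0.49 for G2 and mitosis and 0.746 for the other 4. The ranges of adjusted p that follow leave this alternative out. The secretory factors also failed with array weights (0.425), the mean of probes (0.363), median scaling (0.562) and the stricter filter (0.219), and in the range of 0.407 to 0.459 over left-out replicates failed without GFP replicate 3 or 5SA-Atoh1 replicate 1 (adjusted p = 0.0524 and 0.0527). Over these other alternatives their adjusted p ran from 0.0162 to 0.118. Goblet genes failed with array weights (0.368), median scaling (0.512) and outside shifted runs (0.288), with adjusted p from 0.0073 to 0.099. S phase genes failed with median scaling (−0.062) and spike-in scaling (0.179), with adjusted p up to 0.236. G2 and mitosis genes failed under quantile normalization (0.022, adjusted p = 0.185), and cholesterol synthesis under spike-in scaling (0.62). The cause was not tested.

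Calls were also gained. Immediate early genes were called under quantile normalization (adjusted p = 0.0162), detected-probe scaling, the stricter filter, trend and robust fitting, the slide block, slide 1, spike-in scaling and outside shifted runs, and without 5SA-Atoh1 replicate 2 or 3. NOTCH ligands were called under detected-probe scaling, the slide block, slide 1 and outside shifted runs (adjusted p = 0.0389), and inflammatory genes under spike-in scaling (adjusted p = 0.022). MKI67 passed with median scaling, array weights and spike-in scaling, and MYC under quantile normalization (−0.22) and, in the other direction, spike-in scaling (0.362, adjusted p = 0.0441).

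With the replicate block the secretory factors were no longer called (0.437, adjusted p = 0.0503), 3665 genes were higher and 4576 lower, with 509 and 787 at least 2-fold, and no other list or named gene changed its call. Deviations of samples with the same number correlated at −0.31, −0.05 and −0.06, and 0 of 6 samples correlated best with their own number, so the numbers were not taken as pairs.

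Besides the S phase median under spike-in scaling and MUC6, both called in the main setting, the directions that turned were those of results not called there. The camera direction of the immune markers turned under detected-probe scaling (median −0.275), trend and robust fitting (−0.219), the mean of probes (−0.175), no filter (−0.111), normexp (−0.07), quantile normalization (0.003), the slide block and slide 1 (−0.056), spike-in scaling (0.147) and outside shifted runs (−0.185), and −0.336 to −0.122 was the range over left-out replicates. For p53 targets it turned with trend and robust fitting (−0.052), the mean of probes (−0.065), median scaling (0.073), normexp (−0.017), the slide block and slide 1 (0.035) and spike-in scaling (0.315), with −0.09 to −0.031 over left-out replicates. Hair cell genes turned under median scaling (−0.029) and the stricter filter (−0.154), early neuronal genes under normexp (−0.059) and quantile normalization (−0.03), and enterocyte genes under quantile normalization (−0.056) and the slide block (−0.07). Quantile normalization turned protein folding (−0.072) and enteroendocrine genes (−0.043). NOTCH receptors and targets, −0.159 to −0.076 over left-out replicates, turned without 5SA-Atoh1 replicate 1. CDKN1A turned with array weights (0.014), quantile normalization (0.072) and spike-in scaling (0.235), MYC with median scaling (0.12), spike-in scaling (0.362) and over left-out replicates (−0.023 to 0.024), MKI67 under quantile normalization (−0.036), the slide block and slide 1 (−0.015), and MUC6 under spike-in scaling (0.012). The cause was not tested. Of the 142 named genes, 6 lost their call with the slide block, 8 within slide 1 and 10 under spike-in scaling. Genes near the background, where normexp and the scanner's own correction differ, limit the size of the folds.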

Other observations

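The families and the difference between cell cycle lists were chosen as tests after the data were seen, as were the tests of the slide, of base composition, of copy number as the whole cause of the 2-fold genes or of the runs, and of diverged cultures. The test of 2-fold genes within runs was chosen before its result was seen.

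Gene families outside the fixed lists, 16 in all, were picked after the table of all genes had been read, so their tests describe these samples only. Cytosolic ribosomal protein genes rose together by small amounts, 48 of 79 rising and 2 falling with a median of 0.22 (camera adjusted p = 2.7e-06, adjusted p = 0.32 with an estimated correlation). A median of this size may depend on the normalization. Under quantile normalization the bright genes MYC and CLDN4 went from −0.005 to −0.22 and from 0.88 to 0.64, and the dim HES1 from 0.79 to 1.05. No value of the families under that normalization is given. S100 genes, which encode small calcium-binding proteins, had 10 risers and 0 fallers of 14 (median 0.44, adjusted p = 0.0019, adjusted p = 0.14 with an estimated correlation), with S100A4 rising by 3.39, S100A6 by 1.44 and S100P by 1.26. All 10 metallothionein genes, which bind zinc and copper, fell (median −0.93, adjusted p = 0.0019, adjusted p = 0.32 with an estimated correlation), MT2A by 1.53 and MT1F by 1.25, although their probes may bind each other's transcripts, and the median stayed at −0.56 under spike-in scaling. Zinc finger genes of the ZNF series had 176 fallers and 60 risers of 384 (median −0.16, adjusted p = 0.02, adjusted p = 0.14 with an estimated correlation), a direction that turned to 0.21 under spike-in scaling. Of 30 HOX genes 14 fell and 6 rose (adjusted p = 0.33), with HOXC9 at least 11.7-fold and HOXC8 at least 2.36-fold lower.

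The mean of the G2 and mitosis genes minus that of the S phase genes was −0.99 ± 0.01 on GFP arrays and −0.52 ± 0.02 on 5SA-Atoh1 arrays (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The difference of the list medians lay between 0.34 and 0.37 in the main setting and all alternatives.

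Shifted runs of neighbouring genes were the most surprising feature. The slides as the cause are argued against by slide 1 alone, where 86% of the genes in runs had neighbours past the same limit in the same direction. Base composition of genes or probes was not measured. The genes of chromosomes 13 and 18, which are poor in G and C like chromosome 4, had a median 0.001 from that of all genes. This speaks only against a shift of every such chromosome, and cannot decide on base composition within the runs. A candidate explanation is a difference in copy number between the cultures. In the runs 63.3% of the genes were called in the direction of the run, but runs were defined by such shifts, so this share decides nothing. No DNA was measured, and a regional effect of 5SA-Atoh1 on transcription cannot be told apart from this.

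For the 1308 genes changed at least 2-fold, such runs may contribute in part, since 13.9% lay in a run of their own direction. Of all placed genes, 9.97% lay in a run of either direction, which is a wider measure than a run of the gene's own direction. In 100 random orders the share of 2-fold genes was at most 0.229%. Such orders break up the runs themselves, so this does not show that 2-fold genes gather in runs. The neighbours of the 2-fold genes had a median deviation of 0.064 in the gene's own direction. This is no separate test of the runs as the whole cause, since a share of 13.9% in runs already fixed a median below 0.3. The largest window lay 0.68 from all genes, below the log2 change of 1 that each 2-fold gene reached. Cultures that had drifted apart after separate infection could also give differences such as these, and the groups did not overlap for 99.9% of the 2-fold genes, which genes picked for a large change show under any cause. The labels do not say how many infections each group had, and these cannot be told apart.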
